A study of Mus musculus with 8 samples.

How the data were processed

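Cortical cells of adult male C57BL/6 mice were profiled by single-cell RNA sequencing 7 days after midline fluid percussion injury at 1.2 atm, a diffuse traumatic brain injury (TBI) delivered as a pressure pulse onto the exposed dura, or from naive mice. Mice ate chow with 1200 mg/kg PLX5622, an inhibitor of the receptor CSF1R on which microglia depend for survival, or AIN-76A vehicle chow, for 14 days before injury and until the end. The 4 groups (control or TBI, vehicle or PLX5622) hold 2 libraries each, and each library is a pool of 3 mice, so the library is the replicate and n = 2 per group throughout. Per the labels' protocols, mice were perfused, the cortex was dissociated with enzymes, myelin debris was removed by density centrifugation and red cells were lysed before loading on the 10x Genomics 3' v2 platform and sequencing on an Illumina HiSeq.

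The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode; per the submitters' processing notes they come from Cell Ranger and the mm10 genome. The headers of 7 matrix files give Cell Ranger version 3.0.2, and the header of the control PLX5622 replicate 1 matrix has no version line. The lowest total per deposited barcode is 500 UMIs in 6 of the libraries and 502 in TBI PLX5622 replicate 1, but 941 in control PLX5622 replicate 1, so the deposited barcodes of that library start at a greater depth. The setting that removed barcodes below these totals is not given in the sources used here. Genes are named by symbol only (24062 per library), none of the names begins with mt- (0 lines), and a planned limit on mitochondrial UMIs could therefore not be applied. Total UMIs per library ran from 2614176 in TBI PLX5622 replicate 1 to 20961942 in control PLX5622 replicate 2.

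From 40666 deposited barcodes, those with at least 300 genes were kept, and the barcodes with the highest Scrublet doublet scores were removed at 0.8% per 1000 barcodes (2324 barcodes), leaving 38122 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave 39 Leiden clusters at resolution 1, with no batch integration (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, figures with matplotlib 3.10.9). Clusters were named from 20 marker lists and merged into 17 classes with cells. A class name stands for cells that resemble that type by these markers; no annotation of the cells was among the files. The markers were chosen before the data were examined, and the thresholds that turned them into names afterwards. A cluster with leading genes of several classes stayed unnamed and entered no class. The 6 unnamed clusters hold 2703 cells, or 1.78% and 2.63% of the cells of the control vehicle libraries (replicates 1 and 2), 5.24% and 6.52% of control PLX5622, 55.1% and 3.03% of TBI vehicle, and 4.33% and 5.56% of TBI PLX5622. No cluster was named as oligodendrocyte precursors, neural progenitors or erythroid cells.

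UMIs were summed per library and class. Libraries with at least 20 cells of the class entered 1 edgeR fit per class (edgeR 4.0.16 in R 4.3.3; TMM factors, filterByExpr, glmQLFit and glmQLFTest, 4 group means), and a comparison was made where both groups kept 2 libraries, which gave 22 tests in 7 classes. The comparisons were TBI against control on each diet, the mean of both PLX5622 groups against the mean of both vehicle groups (4 libraries each), and the difference of the TBI responses between diets. Benjamini-Hochberg adjusted p below 0.05 counted as changed, and log2 fold changes are given ± SE. CPM values were computed from the class sums. Gene lists (29, plus the 20 marker lists) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists of a class and comparison, and again with an estimated correlation; list members were also counted when adjusted over the list alone. Shares of cells were compared by two-sided exact permutation tests over libraries, adjusted over classes. Intervals on counts are exact Clopper-Pearson intervals at 95% and, like the upper limits from 3 counts, cover counting error only.

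The genes named were chosen by a rule written, like the tests, the lists and the main alternatives, before the data were examined. For each class and comparison it takes up to 10 called genes per direction with the largest fold change, a mean of at least 20 CPM and the same direction in replicates 1 and 2; with under 5 calls, up to 6 genes of smallest p, given as values; up to 4 genes of smallest p per list; and a fixed set of markers. Beside genes that describe clusters, the text names a part of them, 111 genes, of which 110 have a position in the RefSeq annotation of GRCm38.p6, the assembly that mm10 stands for. Genes with near-identical copies whose UMIs the counting could have split or shared are uncertain between copies: Hba-a1 and Hba-a2, C4b and C4a, Ccl2 and Ccl12, Ifit3 and Ifit3b, and Serpina3n and its family.

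Per the series' design text the experiment was completed in 2 experimental replicates, and libraries with the same replicate number deviated together from their group means. The correlation of these deviations was 0.329 to 0.686 over the 6 pairs of groups in microglia, 0.259 to 0.487 in endothelial cells, 0.438 to 0.619 in astrocytes, 0.330 to 0.527 in oligodendrocytes and 0.302 to 0.787 in neurons. It was 0.147 to 0.188 over 3 pairs in T or NK cells and 0.0858 for the 1 pair in fibroblasts. The replicate number was therefore taken to pair the libraries, and values from the same fit with the replicate number as a block stand beside every result that the block changes (in microglia it moved the genes called between diets from 175 to 823). Genes that pass only in that fit were chosen by the same rule applied to its calls.

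The edgeR step without the replicate block was tested on simulated counts with 200 genes changed by known folds. The simulated libraries were drawn independently, without the deviations that libraries of the same replicate number shared in the data. The figures therefore hold for libraries without that structure. The fit with the replicate number as a block was not simulated, so these figures do not cover its calls. For TBI against control on vehicle diet it recovered 10% of 2-fold and 65% of 4-fold changes in microglia (10121 genes), 14% and 78% in astrocytes (11197 genes), 19% and 62% in oligodendrocytes, 15% and 71% in endothelial cells and 1% and 8% in neurons. For PLX5622 against vehicle the shares were 43% and 88% in microglia, 54% and 93% in astrocytes, 48% and 95% in oligodendrocytes, 39% and 88% in endothelial cells and 5% and 60% in neurons. For TBI against control on PLX5622 they were 6% and 50% in microglia, 23% and 77% in astrocytes, 26% and 74% in oligodendrocytes, 18% and 67% in endothelial cells, and 0% and 0% in neurons. False calls exceeded the 5% set in most comparisons. For PLX5622 against vehicle they were 13 of 144 calls in microglia, 12 of 159 in astrocytes, 7 of 150 in oligodendrocytes, 12 of 139 in endothelial cells and 8 of 73 in neurons. For TBI on vehicle they were 14 of 89 in microglia, 7 of 99 in astrocytes, 3 of 84 in oligodendrocytes, 13 of 99 in endothelial cells, 2 of 11 in neurons and 3 of 64 in fibroblasts. For TBI on PLX5622 they were 3 of 59 in microglia, 18 of 118 in astrocytes, 4 of 104 in oligodendrocytes, 7 of 92 in endothelial cells and 9 of 72 in T or NK cells. Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, no filter on low counts, at least 500 genes per cell, doublets kept, Leiden resolution 2 (51 clusters), each library left out in turn, genes with at least 10-fold higher CPM in microglia left out of the other classes, and other denominators for shares. Those chosen after seeing the data were shares over named cells, the reactive microglial cluster alone and oligodendrocytes without the tenth richest in microglial UMIs.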

Results

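Single-cell transcriptomes were collected from the cortex of mice 7 days after midline fluid percussion injury and from naive controls, fed vehicle chow or chow with PLX5622, which blocks CSF1R and depletes microglia. Each of the 4 groups holds 2 libraries from pools of 3 mice. The libraries of replicate 1 held fewer UMIs in total than those of replicate 2 in every group, but with a higher median of UMIs per barcode. The totals were 11990408 and 20745988 UMIs in control vehicle and 4319114 and 20961942 in control PLX5622, and 5387991 and 16845083 in TBI vehicle, and 2614176 and 12954513 in TBI PLX5622 (replicates 1 and 2). After filtering, control vehicle held 4662 and 9071 cells and control PLX5622 held 1337 and 7774. TBI vehicle held 2343 and 7784, and TBI PLX5622 669 and 4482. The design sets injured against uninjured cortex on each diet and asks how the response changes when microglia are depleted. Since the controls were naive, exposing the dura and the pressure pulse cannot be told apart in any comparison of TBI against control.

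The first question was which cells PLX5622 removed. Microglia made up 14.3% ± 9.37 of the cells on PLX5622 and 38.1% ± 8.26 on vehicle (SD, n = 4 libraries each), and every PLX5622 library lay below every vehicle library. Border macrophages, the Mrc1- and Pf4-expressing macrophages of meninges and perivascular spaces, made up 0.127% ± 0.169 against 0.875% ± 0.219. No border macrophage was found in the control PLX5622 libraries. There, 0 of 1337 cells in replicate 1 allows a share of up to 0.224%, and 0 of 7774 in replicate 2 allows 0.0386%. Lymphocytes and neutrophils made up a larger share of PLX5622 libraries. T or NK cells made up 4.59% ± 2.74 against 1.11% ± 0.349, B cells 1.19% ± 0.168 against 0.404% ± 0.322. Neutrophils made up 1.56% ± 1.13 against 0.207% ± 0.142, and astrocytes 39.9% ± 8.64 against 19.8% ± 10.8. For these 6 classes the diets did not overlap (two-sided exact permutation p = 0.0286, the smallest that 70 assignments can give). None of the 17 classes passed adjustment (adjusted p = 0.0810 for each of the 6). Since the loss of microglia raises all other shares, these were also taken over the remaining cells. There only border macrophages (0.164% against 1.46%) and T or NK cells (5.60% against 1.84%) kept apart without overlap. Over cells in named classes except microglia, border macrophages still did (0.176% against 2.11%). T or NK cells overlapped there (5.97% against 2.63%), with 3.82% in TBI vehicle replicate 1 against 2.83% in control PLX5622 replicate 1. The difference in neutrophils went from 1.35 to 0.840 points without control PLX5622 replicate 2, and that in T or NK cells from 3.49 to 2.18 without TBI PLX5622 replicate 1. Shares reflect cells that survived perfusion, enzymatic dissociation and density centrifugation, and the deposited barcodes of control PLX5622 replicate 1 begin at 941 UMIs against 500 to 502 elsewhere.

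**Figure D1:**
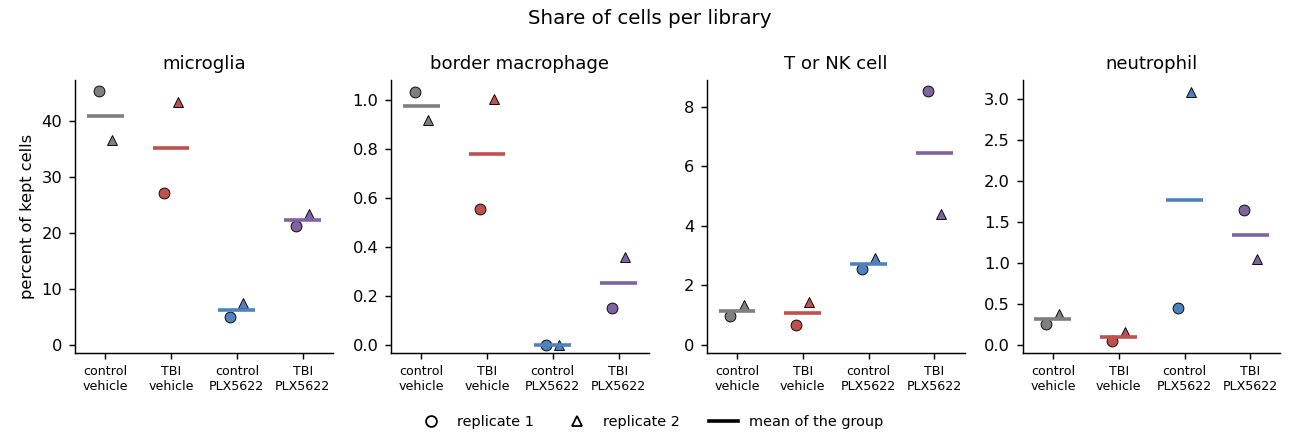
Percent of all kept cells per library (points) and group mean (line) for microglia, border macrophages, T or NK cells and neutrophils in the 4 groups; circles are replicate 1 and triangles replicate 2. The PLX5622 libraries lie between 5.01% and 23.4% microglia and the vehicle libraries between 27.1% and 45.3%.

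The next question was whether injury changed the cellular composition. On PLX5622, microglia made up 22.3% ± 1.53 of cells after TBI and 6.25% ± 1.75 in controls (SD, n = 2 libraries each), and T or NK cells 6.46% ± 2.92 against 2.73% ± 0.267. The T or NK difference of 3.73 points was 1.66 without TBI PLX5622 replicate 1 and 5.79 without its replicate 2. On vehicle, microglia made up 35.2% ± 11.6 after TBI and 41.0% ± 6.19 in controls. In TBI vehicle replicate 1 a single unnamed cluster held 53.9% of the barcodes (exact 95% interval 51.8 to 55.9). Without this library the difference turned from -5.73 to 2.44 percentage points, and over cells in named classes it was 10.6. It was -1.35 and -10.1 without control vehicle replicates 1 and 2, and -13.9 without TBI vehicle replicate 2. Over both diets the microglial difference of 5.16 points (4 libraries against 4, exact permutation p = 0.629) turned to -1.04 without control PLX5622 replicate 1 and to -0.213 without its replicate 2. Astrocytes were a smaller share of all kept cells after injury on both diets, 11.6% against 28.0% on vehicle and 33.4% against 46.5% on PLX5622. Without TBI vehicle replicate 1 the vehicle difference went from -16.4 to -10.2 points. On PLX5622 the larger share of microglia after TBI lowers all other shares. Over cells other than microglia, astrocytes there were a smaller share after TBI in replicate 1 but not in replicate 2. Replicate 2 held 3300 astrocytes and 582 microglia among 7774 cells in control PLX5622. In TBI PLX5622 it held 1639 and 1048 among 4482. Within a diet the smallest p for 2 libraries against 2 is 0.333 in the exact permutation test, so the differences on each diet are given as values only.

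In the microglia that remained on PLX5622, 150 genes rose and 25 fell against vehicle (edgeR, 4 libraries per diet). Among the genes that rose were Hcar2, a hydroxy-carboxylic acid receptor of myeloid cells (log2 fold change 2.55 ± 0.37, adjusted p = 0.0127), the interferon-stimulated Ifi27l2a (2.42 ± 0.37, adjusted p = 0.0144) and Ccl2, a chemokine that attracts monocytes (2.10 ± 0.37, adjusted p = 0.0265). The related Ccl12 rose (2.00 ± 0.31, adjusted p = 0.0144), as did Cxcl10, an interferon-induced ligand of the T cell receptor CXCR3 (1.90 ± 0.33, adjusted p = 0.0238). Htra3, a secreted serine protease, rose by 2.08 ± 0.28, Fgl2 by 1.78 ± 0.31 and Emp3 by 1.77 ± 0.35. The proton-sensing receptor Gpr65 rose by 1.76 ± 0.27 and the cell cycle inhibitor Cdkn1a by 1.62 ± 0.33. The largest decreases were in Csmd3 (-1.83 ± 0.26), Klhdc8b (-1.70 ± 0.26), Upk1b (-1.33 ± 0.26), the transglutaminase Tgm2 (-1.29 ± 0.21) and Crybb1, a marker of adult microglia (-1.14 ± 0.15). Lrba (-1.11 ± 0.15), Fcrl1 (-1.02 ± 0.18), Mlph (-1.01 ± 0.16), Ecscr (-1.01 ± 0.16) and Cd164 (-0.98 ± 0.15) fell as well. Csf1r, the drug's target (chromosome 18, 61105572 to 61131139, GRCm38.p6), stood at 0.18 ± 0.14 and did not pass.

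The homeostatic microglial list moved down with 14 of its 18 members lower (median -0.43, adjusted p = 3.59e-08; adjusted p = 0.312 with an estimated correlation). Of them 5 members fell over all genes and 8 when adjusted over the list alone. The purinergic receptor P2ry12 (chromosome 3, 59216271 to 59262985) fell by 0.92 ± 0.10 and Tmem119 by 0.76 ± 0.14. Cx3cr1 was at -0.37 ± 0.11 (adjusted p = 0.196; 0.0124 with the replicate number as a block). C1qa was at -0.11 ± 0.17, which turned to 0.02 without control vehicle replicate 2 and to 0.06 without TBI vehicle replicate 2. Ribosomal protein genes formed the most uniform group: all 52 were higher (median 0.76). Of these 45 rose over all genes and 49 when adjusted over the list alone (adjusted p = 1.51e-68; adjusted p = 0.111 with an estimated correlation). Inflammatory cytokines and NF-kB targets had a median of 0.97 with 4 of 21 rising over all genes and 11 when adjusted over the list alone (adjusted p = 1.69e-09; adjusted p = 0.123 with an estimated correlation). Immediate early and dissociation genes, which enzymatic dissociation can induce, were higher beside them in 20 of 24 members (median 0.75, adjusted p = 0.00773; adjusted p = 0.737 with an estimated correlation). Over all genes 0 rose and 0 when adjusted over the list alone, and with the block 15 rose over all genes and 17 when adjusted over the list alone. Nuclear genes of oxidative phosphorylation (median 0.32, 2 of 33 rising, 3 when adjusted over the list alone), the type I interferon response (0.66, 2 of 31, 5 alone) and the disease-associated microglial list (0.46, 1 of 23, 7 alone) were also higher, with adjusted p = 0.386, 0.386 and 0.405 with an estimated correlation. Isg15 (0.59 ± 0.35) and Irf7 (0.54 ± 0.34) did not pass. The receptor kinase Axl (1.70 ± 0.42) passed with the replicate number as a block (1.68 ± 0.27, adjusted p = 0.000338). It also passed without control vehicle replicate 1 (1.34) or 2 (2.54).

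In microglia 585 genes rose and 238 fell between diets with the replicate number as a block, among them all 175 of the unblocked fit with the same sign. The unblocked count was 87 without control vehicle replicate 1, 88 and 81 without control PLX5622 replicates 1 and 2, 83 and 92 without TBI vehicle replicates 1 and 2. It was 0 without either TBI PLX5622 library (1011 and 1140 genes at unadjusted p below 0.05 without replicates 1 and 2). Hcar2, Csmd3, Crybb1, Lrba, Cd164 and P2ry12 passed without any 1 of the other 6 libraries. In each vehicle library the cluster led by Crybb1, Cx3cr1 and P2ry12 held the most microglia. A cluster led by Gpr34 and P2ry13 held 40.1% and 27.3% of them in replicate 2 of control and TBI vehicle. In replicate 1 it held only 0.946% and 0.316%. PLX5622 microglia lay mostly in a cluster led by Cst7, Ccl12 and Clec7a, except in control PLX5622 replicate 1, where a cluster led by Ccl4, Ccl3 and Atf3 held most. Within the Cst7 cluster alone edgeR called 0 genes between diets (308 at unadjusted p below 0.05; 10 rose and 14 fell with the block; DESeq2 was not run there).

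**Figure D2:**
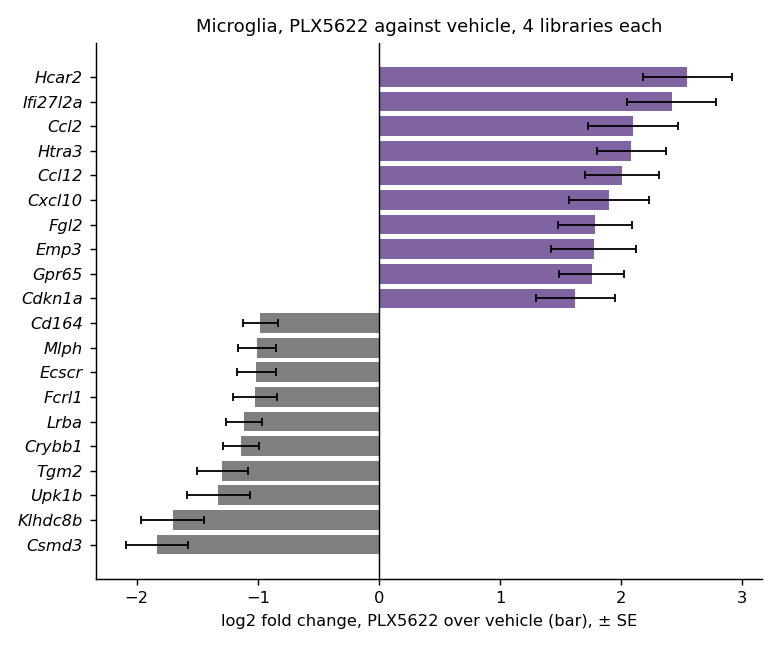
Log2 fold change of PLX5622 over vehicle in microglia (bars) with its standard error, 4 libraries per diet, for the 10 genes of largest change in each direction chosen by the rule. Values run from 2.55 for Hcar2 to -1.83 for Csmd3.

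The other cell classes were then compared between diets. In oligodendrocytes 35 genes fell and 0 rose on PLX5622 (228 genes at unadjusted p below 0.05; DESeq2 32 lower and 0 higher). All 35 have at least 10-fold higher CPM in microglia. Tmem119 fell by 4.20 ± 0.40 (adjusted p = 0.000321), Selplg by 3.95 ± 0.35, P2ry12 by 3.74 ± 0.34, and Cx3cr1 by 3.65 ± 0.33. Rgs10 fell by 3.42 ± 0.39, Csf1r by 3.39 ± 0.29, Trem2 by 3.27 ± 0.46, Laptm5 by 3.18 ± 0.43 and the complement genes C1qc and C1qb by 2.92 ± 0.29 and 2.91 ± 0.36. Of the microglial markers, 10 of 11 fell, also when adjusted over the list alone (median -3.07, adjusted p = 1.32e-43; adjusted p = 0.0191 with an estimated correlation). Astrocyte markers were higher (median 0.50; adjusted p = 0.606 with an estimated correlation). With the replicate number as a block 15 genes rose and 81 fell. Complement C4b rose by 1.65 ± 0.24 (adjusted p = 1.18e-06; 1.60 ± 0.39 and 0.194 without the block). The prostaglandin synthase Ptgds rose by 0.40 ± 0.07 (adjusted p = 7.21e-05; 0.40 ± 0.12 and 0.475). The count was 19 without control vehicle replicate 2 and 6 without TBI vehicle replicate 2, where Rgs10 (-3.07), Trem2 (-2.64), Laptm5 (-3.34) and C1qb (-2.59) no longer passed. It was 0 with doublets kept, with the microglial genes left out, or without the tenth of the cells richest in microglial UMIs (243, 126 and 145 genes at unadjusted p below 0.05).

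**Figure D3:**
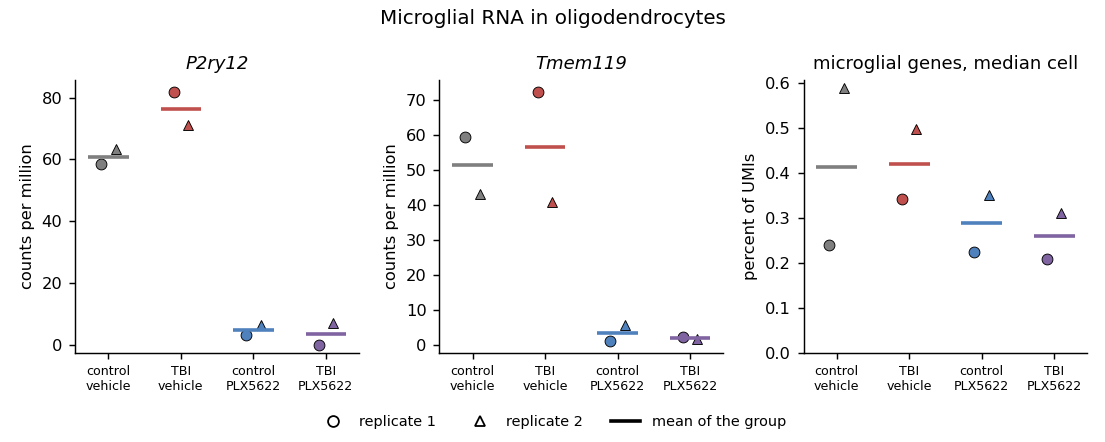
CPM of P2ry12 and Tmem119 in the summed oligodendrocytes of each library, and the percent of UMIs from microglial genes in the median oligodendrocyte; points are libraries and lines group means. The median cell holds 0.210% to 0.352% in PLX5622 libraries and 0.239% to 0.589% in vehicle libraries, higher in replicate 2 of each group.

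Endothelial cells carried fewer microglial UMIs on PLX5622 as well. Fcrls fell by 3.16 ± 0.43 (adjusted p = 0.0395), Tmem119 by 3.12 ± 0.44 (adjusted p = 0.0425) and Cx3cr1 by 2.91 ± 0.39 (adjusted p = 0.0395). P2ry12 was at -2.87 ± 0.48 and Selplg at -2.96 ± 0.55, and the microglial markers had a median of -2.87 (adjusted p = 0.192 with an estimated correlation). With the replicate number as a block all 11 of these markers fell (adjusted p = 0.0111 with an estimated correlation). These 3 were the calls of the unblocked edgeR fit (DESeq2 3), and 16 genes rose and 47 fell with the replicate number as a block. The genes that rose in that fit were led by other transcripts. The iron-binding lipocalin Lcn2 was at 4.72 ± 0.93 (adjusted p = 0.259; 5.55e-09 with the block). The chemokine-binding receptor Ackr1 rose by 4.00 ± 0.36, Lrg1 by 3.94 ± 0.40 and the cholesterol 25-hydroxylase Ch25h by 2.52 ± 0.33. Ifitm1 rose by 2.42 ± 0.25, Scgb3a1 by 1.90 ± 0.30, the elastic fibre gene Fbln5 by 1.60 ± 0.30, the leukocyte adhesion molecule Vcam1 by 1.25 ± 0.15 and the sterol sensor Insig1 by 1.15 ± 0.19. Of 14 endothelial activation genes 12 were higher (median 0.85, adjusted p = 7.21e-08; adjusted p = 0.352 with an estimated correlation). Over all genes 0 rose and 6 when adjusted over the list alone, against 7 and 9 with the block. All 17 cholesterol synthesis genes were higher (median 0.60, adjusted p = 2.00e-12; adjusted p = 0.352 with an estimated correlation), with 0 rising over all genes and 3 when adjusted over the list alone (1 and 6 with the block). Inflammatory genes had a median of 0.31 and a mean of -0.10 (adjusted p = 0.0128; adjusted p = 0.352 with an estimated correlation). Control PLX5622 replicate 1 stood apart. Lcn2 was at 1.94 CPM there and at 208, 50.3 and 344 CPM in the other PLX5622 libraries, and Ackr1 turned from 3.79 to -0.82 without control PLX5622 replicate 2. Without control PLX5622 replicate 1 Lcn2 (5.11), Ackr1 (4.17), Lrg1 (4.14), Ch25h (2.72), Ifitm1 (2.57) and Scgb3a1 (2.05) passed without the block. The 3 calls became 12, 13 and 10 without control vehicle replicate 1, control PLX5622 replicate 1 or 2, and 1 without TBI PLX5622 replicate 2. They became 0 without TBI PLX5622 replicate 1, without TBI vehicle replicate 1 or 2, with doublets kept, and with the microglial genes left out (225, 252, 494, 266 and 191 genes at unadjusted p below 0.05).

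Astrocytes and neurons gave 0 calls between diets by edgeR (244 and 183 genes at unadjusted p below 0.05; DESeq2 2 and 0). In astrocytes 14 genes rose and 115 fell with the replicate number as a block, led by microglial genes. Gpr34 was at -2.67 ± 0.23, P2ry12 at -2.43 ± 0.21, C1qa at -2.18 ± 0.15, Trem2 at -2.17 ± 0.17, Csf1r at -2.12 ± 0.20 and Tyrobp at -2.11 ± 0.13. The Notch target Hes1 rose by 0.56 ± 0.10 (adjusted p = 0.000741), the Notch-modifying Lfng by 0.41 ± 0.09 (adjusted p = 0.00862) and the adhesion molecule Ntm by 0.57 ± 0.09 (adjusted p = 0.000115), each with an adjusted p of 1.00 without the block. Ntm was also among the leading genes of an astrocyte cluster. The mix of astrocyte clusters differed between diets, and that was not told apart from a change within cells. Microglial markers had a median of -2.08 in astrocytes, and all 12 fell in the blocked fit when adjusted over the list alone (adjusted p = 0.0403 with an estimated correlation; 0.147 without the block). Ribosomal protein genes were lower in 51 of 52 members (median -0.20, adjusted p = 1.25e-14; adjusted p = 0.604 with an estimated correlation). Without control vehicle replicate 1 the unblocked astrocyte count was 28. In neurons 49 genes rose and 92 fell with the block. Tmem119 fell by 3.19 ± 0.35 and P2ry12 by 3.06 ± 0.28, and all 12 microglial markers fell (adjusted p = 0.0181 with an estimated correlation; 0.522 without the block). The interneuron genes Kit, Slc32a1 (the GABA transporter of synaptic vesicles) and Cxcl14 rose by 1.66 ± 0.22, 1.40 ± 0.24 and 1.82 ± 0.34. Nuclear oxidative phosphorylation genes (median 0.43) and cholesterol synthesis genes (0.41) were higher in neurons, with adjusted p = 0.410 and 0.0749 with an estimated correlation. The neurons are not the same mixture in all libraries: a cluster led by Meg3 and Snhg11 held most of replicate 2, a Slc17a7 cluster most of replicate 1, and a small cluster led by Npy, Vip, Sst and Gad1 lay beside them.

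Injury on vehicle diet was compared next, 2 libraries against 2. Interferon genes led the microglial comparison in the fit with the replicate number as a block, but the list was lost with an estimated correlation (adjusted p = 0.137; 0.185 with the block). With the replicate number as a block, Cxcl10 (chromosome 5, 92346638 to 92348889) rose by 3.78 ± 0.31 (adjusted p = 3.21e-06; 3.77 ± 0.46 and 0.176 without the block) and Ifi27l2a by 2.66 ± 0.26 (adjusted p = 2.13e-05). The transcription factor Irf7 rose by 2.37 ± 0.28, the nucleic acid sensor Zbp1 by 2.76 ± 0.37 and the ubiquitin-like Isg15 by 1.87 ± 0.28. Of 31 interferon genes 30 were higher (median 1.56, adjusted p = 7.24e-47; adjusted p = 0.137 with an estimated correlation). Over all genes 0 rose and 22 when adjusted over the list alone, and 20 and 28 did with the block. Ifit3 (2.24 ± 0.26), Ifi204 (2.37 ± 0.31), the antiviral Ifitm3 (2.26 ± 0.31), Slfn5 (1.84 ± 0.28) and Rtp4 (1.58 ± 0.22) were among them, each from the blocked fit. The inflammatory list followed (median 0.73, adjusted p = 1.17e-11; adjusted p = 0.137 with an estimated correlation). Of its 21 members 0 rose over all genes and 2 when adjusted over the list alone. With the block these were 7 and 15, including the T cell chemoattractant Ccl5 (2.82 ± 0.37) and Ccl12 (1.95 ± 0.31). Immediate early and dissociation genes were higher too, in 20 of 24 members (median 0.30, adjusted p = 0.0267; adjusted p = 0.774 with an estimated correlation; 0 rose over all genes and 6 with the block). So were heat shock genes, in 14 of 17 (median 0.22, adjusted p = 0.0275; adjusted p = 0.397 with an estimated correlation). The cluster led by Crybb1, Cx3cr1 and P2ry12 held the most microglia in each of the 4 vehicle libraries. The Cst7 cluster, whose leading genes include Ccl12 and B2m, lay beside it, and the clusters were not mixed alike in control and TBI. Changes within a cluster were not tested here, so a shift between clusters was not told apart from a change within cells. All 52 ribosomal protein genes were higher (median 0.33; adjusted p = 0.137 with an estimated correlation), Rps29 rising by 0.74 ± 0.12 with the block. Markers of other classes moved in these microglia in the blocked fit. Astrocyte markers were lower in 11 of 12 members (median -0.46, adjusted p = 8.94e-06; adjusted p = 0.380 with an estimated correlation) and endothelial markers in 9 of 10 (median -0.44, adjusted p = 7.44e-05; adjusted p = 0.380 with an estimated correlation). All 9 neuron markers were higher (median 0.35, adjusted p = 0.00395; adjusted p = 0.481 with an estimated correlation). Chchd10, Cxcl14 and Gstm1 fell by 0.95 ± 0.20, 0.89 ± 0.19 and 0.74 ± 0.15 in the blocked fit. Gstm1 was at -0.67 without the block and 0.45 without control vehicle replicate 2. P2ry12 (-0.22 ± 0.14) and Tmem119 (-0.34 ± 0.19) did not pass. Apoe was at 0.52 ± 0.65, with 2.46 in replicate 1, -0.17 in replicate 2 and -0.30 without control vehicle replicate 1, and passed at 2.60 without control vehicle replicate 2. In all, edgeR called 0 genes (151 at unadjusted p below 0.05; DESeq2 6 higher), and 62 rose and 5 fell with the block. Unblocked, 5 and 1 were called without control vehicle replicate 2 or TBI vehicle replicate 1.

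**Figure D4:**
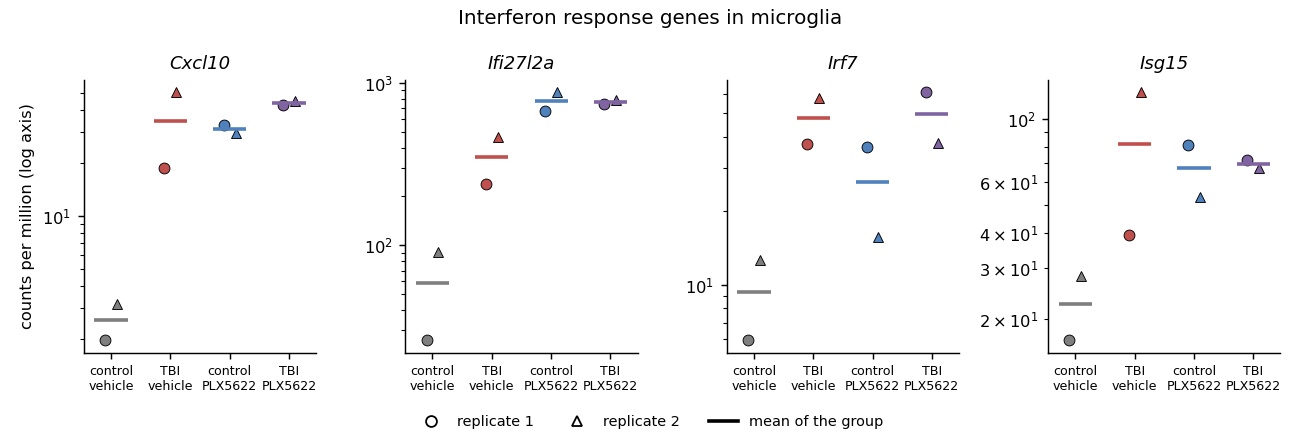
CPM of Cxcl10, Ifi27l2a, Irf7 and Isg15 in microglia, log axis, per library (points) with group means (lines). Cxcl10 stood at 1.97 and 3.17 in control vehicle, at 18.8 and 50.3 in TBI vehicle, at 32.5 and 29.6 in control PLX5622 and at 42.8 and 45.0 in TBI PLX5622 (replicates 1 and 2).

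In astrocytes of injured vehicle mice 23 genes rose and 2 fell with the replicate number as a block. Among them were complement C4b (chromosome 17, 34728139 to 34743902) by 1.70 ± 0.21 (adjusted p = 2.03e-05), the intermediate filaments Gfap by 1.66 ± 0.31 (adjusted p = 0.00699) and Vim by 1.07 ± 0.20 (adjusted p = 0.00822). The protease inhibitor Serpina3n rose by 2.01 ± 0.36 (adjusted p = 0.00435), Ifitm3 by 1.44 ± 0.18 and the taurine transporter Slc6a6 by 1.10 ± 0.24. Carboxypeptidase Cpe rose by 0.97 ± 0.14 and Igfbp5 by 0.95 ± 0.20, while the nuclear RNA Neat1 fell by 0.66 ± 0.15. Gfap, C4b, Cpe and Igfbp5 also led a small astrocyte cluster. The mix of astrocyte clusters differed between control and TBI, and that was not told apart from a change within cells. Without the block edgeR called 0 (218 genes at unadjusted p below 0.05; DESeq2 0). Of 15 reactive astrocyte genes 13 were higher (median 0.46, adjusted p = 7.72e-05; adjusted p = 0.443 with an estimated correlation). Over all genes 0 rose and 1 when adjusted over the list alone (3 and 7 with the block). All 21 interferon genes were higher (median 0.71, adjusted p = 1.01e-14; adjusted p = 0.190 with an estimated correlation; 0 rose over all genes, 0 when adjusted over the list alone, 3 and 9 with the block). Neuron markers (median 1.01) and oligodendrocyte markers (0.46) were higher in the same cells, with adjusted p = 0.276 and 0.149 with an estimated correlation.

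In oligodendrocytes of injured vehicle mice 12 genes rose and 2 fell with the replicate number as a block, and edgeR called 0 without it (168 at unadjusted p below 0.05; DESeq2 0). Among the blocked calls were haemoglobin Hba-a1 (3.18 ± 0.26; -1.47 without TBI vehicle replicate 2 against 3.46 in the unblocked fit), C4b (1.78 ± 0.42, adjusted p = 0.0493; -0.62 without TBI vehicle replicate 2 against 1.94). The others included the myelin-associated protease Klk6 (0.99 ± 0.21), the MHC light chain B2m (0.78 ± 0.16) and Ptgds, which fell by 0.56 ± 0.10. The injury-responsive oligodendrocyte list was higher in 10 of 14 members (median 0.23, adjusted p = 0.0140; adjusted p = 0.749 with an estimated correlation), with 0 changing over all genes, 3 rising and 1 falling when adjusted over the list alone. Neuron markers were higher here too (median 0.84; adjusted p = 0.481 with an estimated correlation). Ribosomal protein genes had a median of -0.10 and a mean of 0.00. In endothelial cells edgeR and DESeq2 called 0 genes (112 by edgeR at unadjusted p below 0.05). Only Cytl1, which led a small endothelial cluster with Gkn3 and Fbln5, fell with the block (-2.66 ± 0.31, adjusted p = 0.000559; 0.34 without control vehicle replicate 2 against -2.21 in the unblocked fit). That cluster held a smaller part of the endothelial cells after TBI in both replicates. A shift in their mixture was therefore not told apart from a change within cells. Igfbp3 was at -1.13 ± 0.35. In neurons, where edgeR and DESeq2 called 0 (15 by edgeR at unadjusted p below 0.05), the neuropeptide genes Vip, Sst and Tac2 fell by 3.92 ± 0.37, 3.03 ± 0.52 and 2.72 ± 0.40 with the block. Each of them led the small interneuron cluster, and a shift in the mixture of neurons was not told apart from a change within cells. Sst and Tac2 turned to 0.30 and 3.28 without control vehicle replicate 2, from -2.38 for both in the unblocked fit. In fibroblasts the chemokine Ccl5 (chromosome 11, 83525778 to 83530518) rose. Ccl5 was also among the leading genes of a T or NK cell cluster, and whether its UMIs here came from such cells was not tested. In the fibroblasts Ccl5 held 0 of 656683 UMIs in both control vehicle libraries together and 104 of 605001 after TBI (172 CPM). That is at least 37.6-fold higher against 3 counts over the group (adjusted p = 0.0302; 0.000492 with the block). It was the only call (DESeq2 0; 0 without either control vehicle library and with doublets kept, 115, 190 and 214 at unadjusted p below 0.05; 21 and 72 calls without TBI vehicle replicates 1 and 2). Col3a1 (1.80 ± 0.39) and Spp1 (-1.56 ± 0.33) passed only without TBI vehicle replicate 2 (2.29 and -2.14).

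Injury was then compared on PLX5622. In microglia edgeR and DESeq2 called 0 genes (251 by edgeR at unadjusted p below 0.05; 1 call without either control vehicle library), and with the replicate number as a block 2 rose and 8 fell. The chemokine Cxcl16 rose by 1.24 ± 0.21 (adjusted p = 0.0242; 1.23 ± 0.25 without the block) and the inhibitory receptor Cd72 by 1.64 ± 0.29 (adjusted p = 0.0339). S100a10 fell by 1.88 ± 0.31, the tight junction gene Cldn5 by 1.80 ± 0.30, and Cnn2 by 1.42 ± 0.25. Igfbp4 fell by 1.17 ± 0.20, Klk8 by 1.00 ± 0.18, the transcription factor Klf2 by 0.96 ± 0.18 and the kinase Sgk1 by 0.94 ± 0.14. Klf2, at -0.74 in the unblocked fit, turned to 0.19 without control PLX5622 replicate 1 and to 0.01 without TBI PLX5622 replicate 2. All 23 disease-associated microglial genes were higher after injury (median 0.90, adjusted p = 8.90e-10; adjusted p = 0.539 with an estimated correlation). Over all genes 0 rose and 0 when adjusted over the list alone, against 0 and 14 with the block. Apoe was at 1.90 ± 0.68 (called at the same value without either control vehicle library), the secreted Spp1 at 3.35 ± 1.51 and the MHC class II chaperone Cd74 at 1.73 ± 0.76. The cluster led by Cst7, Clec7a and Lpl, which are of this kind, held the most microglia in both TBI PLX5622 libraries and in control PLX5622 replicate 2, and the Ccl4 cluster in control PLX5622 replicate 1. The mix of clusters differed between control and TBI in both replicates, and changes within clusters were not tested for this comparison. The interferon list had a median of 0.53, with 27 of 31 members higher (adjusted p = 2.83e-06; adjusted p = 0.539 with an estimated correlation) and 0 rising in any count. Endothelial markers (median -1.30) and astrocyte markers (-0.67) were lower in these microglia, with adjusted p = 0.548 and 0.648 with an estimated correlation.

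In the other classes on PLX5622 the unblocked edgeR fit called 0 genes after injury. There were 158 at unadjusted p below 0.05 in endothelial cells (DESeq2 1), 121 in oligodendrocytes, 68 in astrocytes, 129 in neurons and 83 in T or NK cells (DESeq2 0 in each). With the replicate number as a block 8 genes rose and 1 fell in endothelial cells. The apelin receptor Aplnr rose by 3.90 ± 0.48 (adjusted p = 0.00111; 4.12 ± 0.58 and 0.118 without the block) and elastin Eln by 1.64 ± 0.26. Eln was among the leading genes of the small Cytl1 cluster, which held a larger part of the endothelial cells after TBI in both replicates. That shift was not told apart from a change within cells. Ccl19 rose by 2.52 ± 0.46, Fth1 by 0.83 ± 0.13, Ctla2a by 0.73 ± 0.13, Vcam1 by 1.09 ± 0.20 and Hba-a1 by 2.12 ± 0.28, and the metal-binding Mt1 fell by 0.82 ± 0.13. Vcam1 and Hba-a1, at 1.11 and 2.16 in the unblocked fit, turned to -0.92 and -2.60 without TBI PLX5622 replicate 2. The endothelial count was 6 without control PLX5622 replicate 2 and 2 without TBI PLX5622 replicate 2. Endothelial activation genes were higher in 12 of 14 members (median 0.72, adjusted p = 0.00953; adjusted p = 0.628 with an estimated correlation; 0 rose over all genes and when adjusted over the list alone, 1 and 6 with the block). In oligodendrocytes 4 genes rose and 12 fell with the block. Hba-a1 rose by 5.15 ± 0.25 and C4b by 1.23 ± 0.26. An unnamed cluster was led by Hba-a1, Hba-a2 and Alas2. It held 0.150% and 0.553% of the cells in control PLX5622 and 1.05% and 1.81% in TBI PLX5622 (replicates 1 and 2). Whether the Hba-a1 UMIs in this and the other classes came from such cells was not tested. The choroid plexus transcript Ttr and the astrocyte genes Atp1b2, Aldoc and Slc1a2 fell by 2.40 ± 0.50, 1.40 ± 0.29, 1.09 ± 0.16 and 1.05 ± 0.16, beside a median of -0.71 for astrocyte markers (adjusted p = 0.614 with an estimated correlation). Astrocytes gave 1 gene that rose and 3 that fell with the block, with Hba-a1 at 2.36 ± 0.30.

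In neurons on PLX5622 5 genes rose after injury with the replicate number as a block. The GABA synthesis genes Gad1 and Gad2 rose by 2.29 ± 0.36 and 2.51 ± 0.37, Kit by 2.02 ± 0.29 and Slc32a1 by 1.72 ± 0.33. All of these led the small interneuron cluster, whose part of the neurons differed between control and TBI in both replicates. Changes within it were not tested, so these calls do not separate that difference from a change within cells. Microglial markers were higher in the same neurons (median 1.74; adjusted p = 0.537 with an estimated correlation, 0.0351 with the block as well), with 10 of 12 rising when adjusted over the list alone in the blocked fit. Neuron markers had a median of 0.18 (adjusted p = 0.172 with an estimated correlation, 0.0351 with the block). TBI PLX5622 replicate 1 held 21 neurons. In T or NK cells 3 rose and 15 fell with the block. The scavenger receptor Cd163l1, expressed by gamma delta T cells, rose by 2.69 ± 0.56 (adjusted p = 0.00359). The costimulatory receptor Tnfrsf4 fell by 2.77 ± 0.47 (adjusted p = 9.40e-05), with -0.08 in replicate 1 and -2.97 in replicate 2. Cd74 fell by 1.92 ± 0.45 in the blocked fit, but was at 2.29 in replicate 1 and -2.12 in replicate 2, and at 6.65 without control PLX5622 replicate 2. Hba-a1 rose by 4.31 ± 0.52. The unblocked T or NK count was 1 and 3 without control PLX5622 replicates 1 and 2, and 7 and 8 without TBI PLX5622 replicates 1 and 2. Astrocyte markers had a median of -1.21 in these cells (adjusted p = 0.382 with an estimated correlation). Among the genes that fell in several classes were Wdr89 and Gm13826 (by 1.36 ± 0.24 and 1.34 ± 0.21 in oligodendrocytes, 1.42 ± 0.25 and 1.27 ± 0.23 in astrocytes, and 1.52 ± 0.31 and 1.54 ± 0.27 in T or NK cells) and the pseudogene Rps15a-ps6 (1.90 ± 0.31 in T or NK cells). Wdr89 stood at 281 CPM in oligodendrocytes of control PLX5622 replicate 1 and at 46.6 to 93.6 in the other libraries.

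Finally the TBI responses were compared between diets by the interaction. In microglia the response of Cxcl10 was lower on PLX5622 than on vehicle by -3.14 ± 0.47 (adjusted p = 0.0105) and that of Ifi27l2a by -2.64 ± 0.36 (adjusted p = 0.00807) with the replicate number as a block (-3.24 ± 0.65 and -2.63 ± 0.71 without it, adjusted p = 1.00 for both). The immediate early gene Fos (-1.35 ± 0.23), the NF-kB inhibitor Nfkbia (-1.21 ± 0.21) and Sgk1 (-1.13 ± 0.19) differed the same way in the blocked fit, each with adjusted p = 0.0261. Of 31 interferon genes 28 responded less on PLX5622 (median difference -1.16, adjusted p = 6.62e-14; adjusted p = 0.429 with an estimated correlation). Over all genes 0 passed and 0 when adjusted over the list alone, against 2 and 7 with the block. Other lists responded less on PLX5622 beside them, none of which held with an estimated correlation. Median differences were -0.80 for immediate early and dissociation genes, -0.43 for heat shock genes, -0.34 for ribosomal proteins and -1.03 for endothelial markers. Isg15 (-1.74 ± 0.71) and S100a10 (-1.50 ± 0.39) did not pass. In uninjured control mice Ifi27l2a stood higher on PLX5622. It was at 675 and 877 CPM in control PLX5622 against 26.1 and 90.9 in control vehicle. After injury it was at 737 and 783 in TBI PLX5622 against 238 and 467 in TBI vehicle. By edgeR and DESeq2 0 microglial genes passed without the block (137 by edgeR at unadjusted p below 0.05), and 6 with it.

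In endothelial cells the interaction passed for Cytl1 alone, with the replicate number as a block (4.48 ± 0.48, adjusted p = 0.000111). It turned from 4.00 to -4.69 without TBI PLX5622 replicate 2 in the unblocked fit. The small endothelial cluster that Cytl1 led held a smaller part of these cells after TBI on vehicle in both replicates. On PLX5622 it held a larger part after TBI in both. A shift in the mixture was not told apart from a change within cells. Igfbp3 (1.93 ± 0.49) and Aplnr (2.95 ± 0.84) did not pass. In neurons 16 genes passed with the block, all with a higher response on PLX5622. They were led by the interneuron genes Vip (4.52 ± 0.49), Cxcl14 (4.12 ± 0.68), Sst (3.27 ± 0.65), Gad2 (3.08 ± 0.51), Gad1 (3.00 ± 0.50) and Kit (2.51 ± 0.42). All of these but Cxcl14 led the small interneuron cluster. Its part of the neurons was larger after TBI on PLX5622 in both replicates, and smaller after TBI on vehicle in replicate 2 only. A shift in the mixture of neurons was not told apart from a change within cells. Sst, at 2.56 without the block, turned to -0.15 without control vehicle replicate 2 and to -8.62 without TBI PLX5622 replicate 2. Microglial markers differed in these neurons too (median 1.5; adjusted p = 0.750 with an estimated correlation, 0.0332 with the block). In astrocytes 2 genes passed with the block, of which Hba-a1 was at 3.16 ± 0.47 and turned from 2.75 to -2.34 without control vehicle replicate 2 in the unblocked fit. The interferon list responded less on PLX5622 in astrocytes too (median difference -0.65, 19 of 21 lower, adjusted p = 9.31e-05, adjusted p = 0.490 with an estimated correlation). Of its members 0 passed over all genes and when adjusted over the list alone, 1 and 2 with the block. Markers of other classes moved as far in these astrocytes. Median differences were -0.82 for neuron, -0.79 for oligodendrocyte and -0.71 for endothelial markers and -0.77 for myelin genes, and none of these lists held with an estimated correlation. Without the block edgeR and DESeq2 called 0 genes in endothelial cells, neurons, astrocytes and oligodendrocytes (117, 88, 101 and 116 by edgeR at unadjusted p below 0.05), and 1 endothelial gene passed without TBI PLX5622 replicate 2. Oligodendrocytes gave 0 with the block as well.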

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

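The tests of the large unnamed cluster were chosen after it was seen. For the free microglial RNA the comparison within replicate numbers, for doublets the requirement on the fold, and for the reactive cluster the check on genes not used for clustering were added after their values were seen.

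Microglial genes were lower in oligodendrocytes on PLX5622. The median oligodendrocyte held 0.274% ± 0.0684 of its UMIs from microglial genes on PLX5622 and 0.417% ± 0.156 on vehicle, a difference of -0.142 points (exact p = 0.143 over 70 assignments; 0.0556 within replicate numbers, the smallest that 36 can give). The ranges overlapped, 0.210% to 0.352% against 0.239% to 0.589%, which the bound written beforehand counted against free microglial RNA; that bound ignored the levels of the replicate numbers, within each of which both PLX5622 libraries lay below both vehicle libraries, so this source stays open and cannot be told apart from others. Without the tenth of cells richest in microglial UMIs 0 of 24 tested genes stayed called by edgeR (145 genes at unadjusted p below 0.05, DESeq2 not run). Their median fold went only from -2.91 to -2.03, while the median standard error rose from 0.374 to 0.626. The tenth of oligodendrocytes with the most UMIs of microglial genes held 40.6% to 68.1% of these UMIs in vehicle libraries. In PLX5622 libraries it held 23.2% to 32.9%. Of all UMIs, 17.1% to 19.4% lay in the tenth of cells with the most UMIs. A small cluster of 46 cells named as oligodendrocytes also carried microglial markers. It held 3.43% and 5.13% of the oligodendrocytes in control and TBI vehicle, against 0.344% and 0.761% in control and TBI PLX5622. Whether its barcodes held both cell types was not tested. Doublets with microglia may therefore be a part of the source, above all in vehicle libraries, and how large a part is not settled. Of 35 splits of the libraries 2 called as many genes, the real split (55) and the replicate-number split (998), so over all splits chance was not excluded.

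Genes changed in the microglia of PLX5622 libraries. Within the reactive cluster led by Cst7 the called genes moved by a median of 0.0608 in the direction of the class, against 0.837 in the whole class (166 of 175 tested, 107 with the same sign; 0 called by edgeR, 308 at unadjusted p below 0.05; DESeq2 not run), and the 107 genes not used for clustering by 0.0563 against 0.802. A larger part of reactive cells among the microglia may carry most of the change. Cells of a cluster are grouped by their expression, so smaller folds within it do not by themselves show this. Changes within the other microglial clusters were not tested. Whether the drug made cells reactive or spared reactive cells was not tested either. Free RNA of astrocytes, oligodendrocytes, endothelial cells and neurons was argued against as the main source, since 76.7% of the higher genes had more CPM in microglia than in each of these (115 of 150); the rarer classes were not compared. Of 35 splits 2 called as many genes, the real split (222) and the replicate-number split (993), so over all splits chance was not excluded.

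In every class tested the split with the highest count followed the replicate number, at 993 genes in microglia, 998 in oligodendrocytes, 500 in endothelial cells, 2291 in astrocytes and 2819 in neurons, which points to a structure of the libraries. In endothelial cells 3 of 35 splits called as many genes as the real split (5), so chance was not excluded. In astrocytes and neurons the real split called 0 by edgeR (the 4-group fit had 244 and 183 genes at unadjusted p below 0.05 and DESeq2 2 and 0), which all 35 splits reach by construction, so this count says nothing there. Among the 18 splits that part the replicate numbers as the real split does, the highest other counts were 0 in microglia, 1 in oligodendrocytes and 5 in endothelial cells, against 222, 55 and 5 in the real split, and 18 splits are too few for a share under 0.05. The real comparison with the replicate number as a block called 823, 96, 63, 129 and 141 genes in these classes.

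A large unnamed cluster. In TBI vehicle replicate 1, 1262 barcodes outside the comparisons (53.9% of the library) formed a cluster with UMIs of C1qa in 100% of barcodes, Ttr in 98.8% and Snap25 in 33.3%. Its expression followed the sum of all other cells of the library (Pearson r = 0.943; 0.824 with microglia, the closest class), as droplets with free RNA and no cell may do. Damaged cells of 1 class were argued against, since 7 classes had at least 3 markers in over 10% of the barcodes. No biological explanation was tested.

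The other results that stood out are given as values. An unnamed proliferating cluster of 326 cells, 238 in control PLX5622 replicate 2 and 61 in TBI PLX5622 replicate 2, held Mki67 in 47.5%, Top2a in 56.7%, Birc5 in 79.1% and C1qa in 96.6% of cells, and lay outside the comparisons. The share of B cells after TBI was lower on vehicle (-0.405 points) and higher on PLX5622 (0.261), and the difference was not tested. The TBI response differed between diets by camera for the following lists, none of which held with an estimated correlation without the replicate block (adjusted p = 0.178 to 0.994). With the block the microglial and neuron markers in neurons held (adjusted p = 0.0332 for both). In microglia the median differences were -1.16 for interferon genes, -0.46 for inflammatory genes, -0.37 for reactive astrocyte genes, -0.41 for blood-brain barrier genes, -0.50 for cholesterol synthesis, -0.80 for immediate early genes, -0.43 for heat shock genes, -0.24 for nuclear oxidative phosphorylation, -0.34 for ribosomal proteins, -0.72 for proliferation and -1.03 for endothelial markers. In astrocytes they were -0.65 for interferon genes, -0.77 for myelin, -0.50 for injury-responsive oligodendrocyte genes, -0.23 for glucocorticoid genes, -0.25 for oxidative stress, -0.26 for oxidative phosphorylation, -0.30 for ribosomal proteins, -0.71 for endothelial, -0.79 for oligodendrocyte, 0.34 for oligodendrocyte precursor and -0.82 for neuron markers. In neurons they were 0.34 for oxidative phosphorylation, 0.30 for ribosomal proteins, 1.5 for microglial markers and 0.36 for neuron markers. Oligodendrocytes had -0.96 for astrocyte markers and endothelial cells 0.079 for ribosomal proteins.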

How the results depend on the processing

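Shares over named cells, the reactive microglial cluster alone and oligodendrocytes without the cells richest in microglial UMIs were chosen after the data were seen. Causes of the changes were not tested. Counts below run in the order TBI on vehicle, TBI on PLX5622, PLX5622 against vehicle, and interaction. Genes called with the replicate number as a block were 67, 10, 823 and 6 in microglia, 1, 9, 63 and 1 in endothelial cells, 25, 4, 129 and 2 in astrocytes, and 3, 5, 141 and 16 in neurons. They were 14, 16 and 96 in oligodendrocytes (first 3) and 18 in T or NK cells (TBI on PLX5622). With no filter on low counts they were 53, 36, 489 and 28 in microglia, 6, 22, 76 and 6 in endothelial cells, 16, 9, 83 and 2 in astrocytes, 4, 9, 94 and 1 in oligodendrocytes, 4, 3, 37 and 3 in neurons, 12 in T or NK cells and 23 in fibroblasts. DESeq2 called 6 genes in microglia (TBI on vehicle), 1 in endothelial cells (TBI on PLX5622), 2 in astrocytes (PLX5622) and 0 in fibroblasts (48 at unadjusted p below 0.05). With doublets kept edgeR called 0 in endothelial cells and oligodendrocytes on PLX5622 and 0 in fibroblasts (266, 243 and 214 at unadjusted p below 0.05; DESeq2 not run). With at least 500 genes per cell fibroblasts had 3. With the microglial genes left out endothelial cells and oligodendrocytes had 0 on PLX5622 (191 and 126 at unadjusted p below 0.05), trimmed oligodendrocytes 0 (145) and the reactive cluster alone 0 (308), all by edgeR. With an estimated correlation 1 gene list passed in oligodendrocytes on PLX5622 and 0 in the other 21 tests, against 1 to 19 at the preset correlation. With the block and an estimated correlation 2 passed in endothelial cells, 1 in astrocytes, 1 in oligodendrocytes and 2 in neurons on PLX5622, 3 in neurons after TBI on PLX5622 and 3 for the interaction in neurons, and 0 elsewhere. With the block the lists past the threshold moved to 17 in T or NK cells, 12, 11 and 8 in endothelial cells (all but TBI on PLX5622), 11 and 17 in astrocytes (last 2), 12 and 9 in oligodendrocytes (TBI on PLX5622 and interaction) and 7, 14, 13 and 10 in neurons. Without microglial genes they moved to 3 in endothelial cells and 2 in oligodendrocytes (interaction) and 1 in astrocytes (PLX5622). Among shares, the endothelial difference between diets (2.84 points) turned to -0.225 over cells other than microglia and -3.48 over named cells other than microglia. After TBI on vehicle microglia turned from -5.73 to 10.6 over named cells, border macrophages from -0.194 to 0.140 and 0.760 over named cells with and without microglia, and T or NK cells from -0.0768 to 0.338 and 1.26. Border macrophages after TBI over both diets turned from 0.0297 to -0.0349 without microglia.

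With each library left out in turn, where a lone library left in a group is assumed to vary like the other groups, the genes called ranged from 0 to 5 (TBI on vehicle), 0 to 1 (TBI on PLX5622) and 0 to 194 (PLX5622) in microglia, 0 to 8 in T or NK cells, 0 to 6, 0 to 13 and 0 to 1 in endothelial cells (TBI on PLX5622, PLX5622, interaction), 0 to 72 in fibroblasts, 0 to 28 in astrocytes and 6 to 41 in oligodendrocytes (PLX5622). The share of microglia after TBI ranged from -13.9 to 2.44 points on vehicle and -1.04 to 12.4 over both diets, that of border macrophages from -0.418 to 0.0298 and -0.132 to 0.211, and that of T or NK cells on vehicle from -0.461 to 0.308. Folds that changed sign ranged as follows: on PLX5622 C1qa in microglia -0.27 to 0.057 and Ackr1 in endothelial cells -0.82 to 7.19. After TBI on vehicle they were Gstm1 -1.82 to 0.45 and Apoe -0.30 to 2.60 in microglia, Hba-a1 -1.47 to 10.03 and C4b -0.62 to 3.32 in oligodendrocytes, Cytl1 -9.40 to 0.34 in endothelial cells, and Sst -9.32 to 0.30 and Tac2 -8.86 to 3.28 in neurons. After TBI on PLX5622 they were Klf2 -2.19 to 0.19 in microglia, Vcam1 -0.92 to 3.25 and Hba-a1 -2.60 to 5.24 in endothelial cells, and Cd74 -2.85 to 6.65 in T or NK cells. For the interaction they were Cytl1 -4.69 to 11.19 in endothelial cells, Hba-a1 -2.34 to 5.33 in astrocytes and Sst -8.62 to 13.44 in neurons. Of the settings tried on the named genes 2094 kept direction and call, 252 gained a call, 125 lost it and 19 changed sign. RLE factors and Leiden resolution 2 kept direction and call for 168 of 168 named folds. At 500 genes per cell TBI PLX5622 replicate 1 held too few neurons, and no value is given for the 3 comparisons that need it.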

Other observations

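The tests of the large unnamed cluster and the comparison of replicate numbers within oligodendrocytes were chosen after the values were seen. In microglia after injury on vehicle 30 of 31 interferon genes were higher (adjusted p = 7.24e-47; adjusted p = 0.137 with an estimated correlation). By edgeR 0 genes were called over all genes (151 at unadjusted p below 0.05; DESeq2 6). Cxcl10 stood at 1.97 and 3.17 CPM in control vehicle, 18.8 and 50.3 in TBI vehicle, 32.5 and 29.6 in control PLX5622, and 42.8 and 45.0 in TBI PLX5622. Ifi27l2a stood at 675 and 877 CPM in control PLX5622, above the 238 and 467 in TBI vehicle. After TBI on PLX5622 the disease-associated list was higher in all 23 members (median 0.90, adjusted p = 8.90e-10; adjusted p = 0.539 with an estimated correlation), and on vehicle in 16 of 23 (median 0.36, adjusted p = 3.02e-05; adjusted p = 0.646 with an estimated correlation). For Cxcl10 the lower response on PLX5622 may reflect a higher level in the uninjured control mice. With the replicate number as a block 6 microglial genes differed in the interaction, and by edgeR without it 0 (137 at unadjusted p below 0.05; DESeq2 0).

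C4b was called after injury in more than 1 class with the replicate number as a block: it rose in astrocytes on vehicle (1.70 ± 0.21), and in oligodendrocytes on vehicle (1.78 ± 0.42) and on PLX5622 (1.23 ± 0.26). C4b on vehicle rested on TBI vehicle replicate 2 in oligodendrocytes, at -0.62 without it. In endothelial cells the activation genes were higher on PLX5622 (median 0.85; adjusted p = 0.352 with an estimated correlation) and after TBI on PLX5622 (median 0.72; adjusted p = 0.628 with an estimated correlation), where Vcam1 turned to -0.92 without TBI PLX5622 replicate 2.

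Control PLX5622 replicate 1 stood apart in several ways. Its deposited barcodes began at 941 UMIs, it held 67 microglia, and Wdr89 and Gm13826 stood at 992 and 911 CPM in them, against 98.3 to 258 and 112 to 414 in microglia of the other libraries. Genes that fell after TBI on PLX5622 in several classes include Wdr89 and Gm13826, and those calls rest partly on this library. Each group held fewer neurons in replicate 1 than in replicate 2, with 21 cells in TBI PLX5622 replicate 1, and their clusters differed from those of replicate 2, and changes within a cluster were not tested. Vip stood at 53.3 and 903 CPM in control vehicle and at 0 and 63.7 in TBI vehicle (replicates 1 and 2).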
